A study of Mus musculus with 40 samples.

How the data were processed

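Hippocampal RNA of 40 mice was hybridised to 1-colour Illumina mouse Ref-8 arrays, with 1 mouse per array per the series' design text. The deposited non-normalized table holds the signal intensity of 25697 probes per array, already background-subtracted per its values, and a detection score per probe. Per the file headers that score is a detection p-value, but it is near 1 for bright probes, so it was read as 1 minus the p. A second deposited table of the authors' values holds signal intensity in linear units. Each of its 40 columns is a straight line of 1 column of the first table, with slopes of 0.668 to 1.26 and residuals up to 0.112. Its column medians ran from 21.5 to 32.3, against 18.2 to 29.3 in the non-normalized table; which scaling produced the slopes is not given in the sources used here. The scanner software is not given in the sources used here either.

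The 2 tables agree on all 28 Tg arrays and disagree on 8 of the 12 inbred arrays, 6 of which change strain. Numbered columns of the non-normalized table were matched to the running number in the sample titles, and value-table columns to accessions. The non-normalized table was the source fixed before the data were examined. After the disagreement was found, the value table was made the source and its inbred comparisons were computed first, giving 15, 54 and 0 probes for DBA against B6, DBA against SJL and SJL against B6. The analysis then returned to the non-normalized table after the results of both had been seen, so this choice was not blind. A test on Tg arrays, chosen afterwards, is given in the closing section.

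Signals were normalized over the 40 arrays together with neqc of limma 3.58.1 in R 4.3.3, with statmod 1.5.0 installed: normexp background correction from the detection p-values, an offset of 16, quantile normalization and log2. Probes with a detection p of at most 0.01 on at least 4 arrays were tested, 13589 in all; 9575 were detected on all 40 arrays, where the series' design text gives 13309 of 25967. Gene names came from the platform annotation: 23978 probes had 1 symbol, 1719 none and 0 several, and 23962 were matched to current symbols by Entrez number. No coordinates are printed, since the tables give none. Where a probe had a detection p above 0.01 on some or all arrays of the dimmer group, its fold change between groups is given as a bound: the brighter group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. Fitted terms, such as slopes and the transgene term, are given as fitted.

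Comparisons used lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05: the 3 strain pairs in 1 fit of the 12 inbred arrays; log10 Abeta40 as a continuous term in the 28 Tg arrays, without and with the 5 backgrounds; contrasts of 75% and 50% DBA mice against the mean of the 3 DBA-free backgrounds; and a transgene term with percent SJL and percent DBA over 40 arrays. Adjusted p-values of single probes are from limma throughout. Strain-distinct probes passed in both DBA contrasts in the same direction, at 0.05 or at the series' thresholds of 0.001 and 1.5-fold. Abeta40 itself was compared with two-sided permutation tests of 100000 resamples, or exact ones within array sets. Replicates are separate mice; replicate numbers only name arrays and pair nothing.

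The 17 gene lists, fixed before the data were examined, hold 324 genes, 249 of them measured, each by its brightest tested probe. They cover amyloid precursor processing and clearance, kinesin and axonal transport, homeostatic and plaque-associated microglia, astrocytes, reactive astrocytes, oligodendrocytes and myelin, excitatory neurons, interneurons, choroid plexus, thalamus, vessel and blood, early genes, heat shock, interferon and antigen presentation, mitochondrial respiration, and known strain-variant genes. They were tested with camera at a preset correlation of 0.01, adjusted over the 17 lists per comparison. Of 136 such tests 11 were called, and none with an estimated correlation.

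Named genes followed a rule fixed before the data were examined. It took the 12 highest and 12 lowest strain-distinct genes whose DBA arrays did not overlap the others, 6 each way for SJL against B6, 10 each way by t for Abeta40, and 8 each way for DBA-rich and for Tg against inbred mice. It also took every tested Klc1 probe, App, Prnp and the leading list members. Atxn1 and Ttr were named after their values were seen.

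The titles' running number gave runs of 8 arrays, inferred from the 8-array format of this chip and chosen after the principal components were seen; the files name no slide, so the planned slide block was not run. Alternatives fixed in advance covered the value table, quantile normalization without background correction at a floor of 16, separate normalization of inbred and Tg arrays, other filters, trend and robust variances, the methods' t-test, other models and references, subsets of mice, and leaving out single arrays. Within groups, arrays correlated at 0.960 to 0.994. On simulated data with known changes in 13589 probes, the strain-distinct step recovered 68.7% of 67 probes changed 1.5-fold, 92.5% of 67 changed 2-fold and 97.0% of 66 changed 4-fold, with 1 false call. The Abeta40 step recovered 100% of 67, 67 and 66 probes changed 1.5-fold, 2-fold and 4-fold per SD of log10 Abeta40, with 8 false calls. These data held no array sets, no background differences among Tg mice and no link of Abeta40 with DBA. Their spread was that of the inbred arrays. The recovery of the Abeta40 step can therefore be overstated for the real Tg arrays. The number of arrays limits the precision.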

Results

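Messenger RNA was profiled in the hippocampus of 40 mice aged 12 months, with 1 mouse per Illumina mouse Ref-8 BeadChip array. Non-transgenic inbred mice of 3 strains, named b6, dba2 and sjl in the labels and here B6, DBA and SJL, contributed 4 arrays each. The other 28 mice carried an APP transgene, which makes the amyloid precursor protein, on mixed backgrounds. Of these, 6 B6-rich mice were 62.5% B6 and 37.5% SJL with no DBA. Another 6 SJL-rich mice (69% SJL, 31% B6) and 6 SJL-richest mice (84% SJL, 16% B6) also carried no DBA. A group of 3 mice was 50% DBA, 42% SJL and 8% B6, and 7 DBA-rich mice were 75% DBA, 9% SJL and 16% B6. Each transgenic (Tg) mouse had a log10 level of amyloid-beta 40 (Abeta40) in its guanidine fraction, the poorly soluble pool. Between 41.5% and 50.0% of the 25697 probes were detected per array, and the median signal before normalization ran from 18.2 to 29.3.

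The arrays fell into 2 sets by their running number. The first principal component held 35.2% of the variance and ranged from -38.6 to -20.9 on arrays 1 to 16, against 7.16 to 37.1 on arrays 17 to 40. All inbred arrays, all SJL-rich Tg arrays and 6 of the 7 DBA-rich arrays were in the later set. All B6-rich, SJL-richest and 50% DBA arrays were in the earlier one. Between DBA-free Tg arrays of the later and the earlier set, limma called 6424 probes, so values within a set, or with runs of 8 arrays as a block, stand beside the Tg comparisons.

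**Figure D1:**
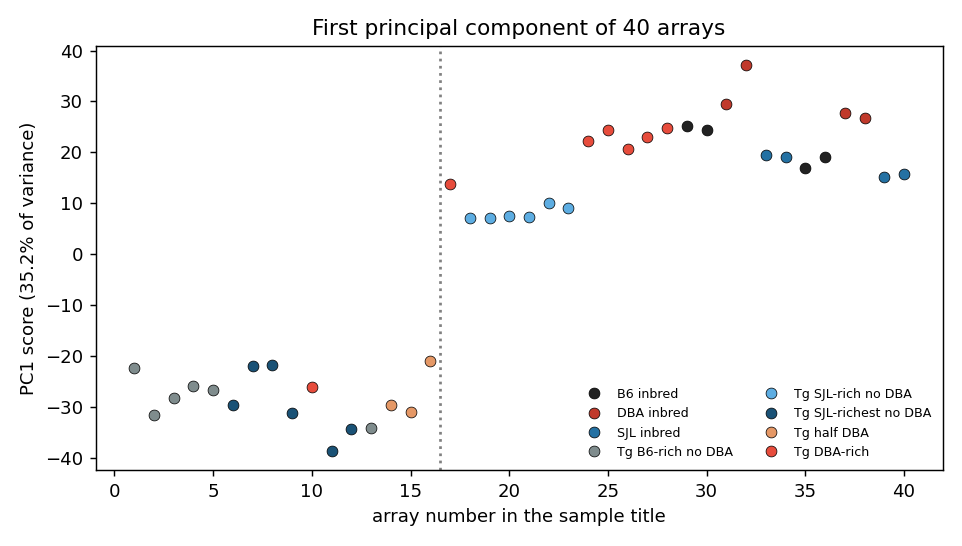
Score on the first principal component of the normalized log2 signals (vertical) against the array number in the sample titles (horizontal), 1 point per array, coloured by group. Arrays 1 to 16 lie at -20.9 or below and arrays 17 to 40 at 7.16 or above.

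The first comparison asked which transcripts differ in DBA mice from both other strains. The largest deficits in DBA that were measured on every array of all 3 strains included Enpp5, 31.8-fold below B6 and 31.4-fold below SJL, and Rps3, a ribosomal protein gene, 20.5-fold and 17.9-fold below. Normalized Enpp5 signal was 6.88 ± 0.29 in DBA against 11.87 ± 0.05 in B6 and 11.85 ± 0.10 in SJL (log2, SD, n = 4 each). Some probes were not detected on any DBA array and have only a bound. Thumpd1 was at least 19.6-fold lower than in either strain, Serpini1, which encodes the neuronal serine protease inhibitor neuroserpin, at least 18.9-fold lower than in B6, and Casp9, an initiator caspase gene, at least 15.4-fold lower than in B6. Tesk1, Znhit3 and Mettl14 were likewise undetected in DBA, at least 14.1-fold, 15.8-fold and 7.88-fold below B6. The proteasome gene Psmb6, Fgfr1op2 and Atf4 were detected on 1 of 4 DBA arrays and were at least 57.0-fold, 23.2-fold and 16.1-fold below B6. Stard7, detected on 3 DBA arrays, was at least 19.6-fold below B6.

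In the other direction, Saraf, a regulator of store-operated calcium entry, was 8.15-fold above B6 and 7.78-fold above SJL in DBA mice. Fam20b was 4.21-fold above B6, Arhgef15 3.66-fold, the acute-phase gene Serpina3n 2.96-fold, Ap5b1 2.88-fold and Lypd1 2.76-fold. Stab2, the class I histocompatibility gene H2-K1, the chemokine receptor gene Ccr6, H2-Ea, Fpr2 and Sfi1 were detected in DBA but on no B6 or SJL array, and stood at least 6.10-fold, 4.88-fold, 2.55-fold, 1.72-fold, 1.68-fold and 1.51-fold above B6. Probes of one gene did not always move alike. Of the 2 other Saraf probes, ILMN_1258965 was lower in DBA than in B6 by a log2 change of -0.55 (adjusted p = 0.000251, limma). Another Rps3 probe, ILMN_2637639, had a log2 change of 0.11 against B6 (adjusted p = 0.484, limma), and the Stard7 probe ILMN_2789125 one of 0.07 (adjusted p = 0.747).

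With limma and Benjamini-Hochberg adjustment at 0.05, 1672 of 13589 probes differed between DBA and B6 (866 lower in DBA) and 1523 between DBA and SJL (730 lower). The first split turned on probes detected on all arrays (595 of 1253 lower) and with runs as a block (908 of 1819). In both comparisons and in the same direction, 606 probes differed, 356 of them lower in DBA. At the thresholds the series states, an adjusted p of 0.001 and 1.5-fold, 227 probes passed, 164 lower and 63 higher, where the series' design text gives 54, 47 lower and 7 higher. The methods' own test gave 111 at those thresholds (92 lower), and limma on probes detected on all arrays gave 119 (84 lower). Both contrasts share the DBA arrays: independent lists would share 93.6 probes, and with the DBA arrays split between the contrasts 288 to 332 were shared. Simulated noise on all 12 arrays, with no strain difference, shared 0. That does not measure the overlap from shared arrays, since noise alone is expected to give few calls in either contrast. The deposited tables disagree on the strain of 6 of the 12 inbred arrays, so these results rest on the order by number. Scores from Tg arrays, on which both tables agree, argue against the accession order (closing section). With the accession-named value table, DBA differed from B6 at 78 probes and from SJL at 85, with 45 in both; with normexp and quantile normalization of that table, the counts were 15, 54 and 13. The choice between tables was settled after both sets of counts had been seen.

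Klc1, which encodes kinesin light chain 1, a cargo-binding subunit of the motor kinesin, was lower in DBA mice by 4 of its 5 probes. Probe ILMN_2605756 read 8.93 ± 0.23 in DBA against 12.31 ± 0.05 in B6 and 12.38 ± 0.07 in SJL (log2, SD, n = 4 each). That was 10.4-fold below B6 (log2 change -3.38 ± 0.10, SE, adjusted p = 6.24e-11, limma) and 11.0-fold below SJL. Probes ILMN_3116826 and ILMN_2671411 had log2 changes of -1.26 and -1.28 against B6 and of -1.41 and -1.32 against SJL. Probe ILMN_3042059 had changes of -0.87 and -0.63. The fifth, ILMN_3163020, did not pass the test, at 0.05 against B6 (adjusted p = 0.867) and -0.08 against SJL (adjusted p = 0.760). The annotation assigns it to another Klc1 transcript than the 4 lower probes. A change of the whole gene was therefore not told apart from one of some transcripts or probes. In the accession-named value table, ILMN_2605756 had a log2 change of 0.0991 in DBA against SJL, so its deficit against SJL is lost with that table. The Tg arrays argue against the inbred order of that table, as the closing section sets out. App, the mouse amyloid precursor gene, differed between DBA and B6 by 0.00 ± 0.07 (SE, adjusted p = 0.986) and the prion protein gene Prnp by 0.03 ± 0.06 (adjusted p = 0.831).

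**Figure D2:**
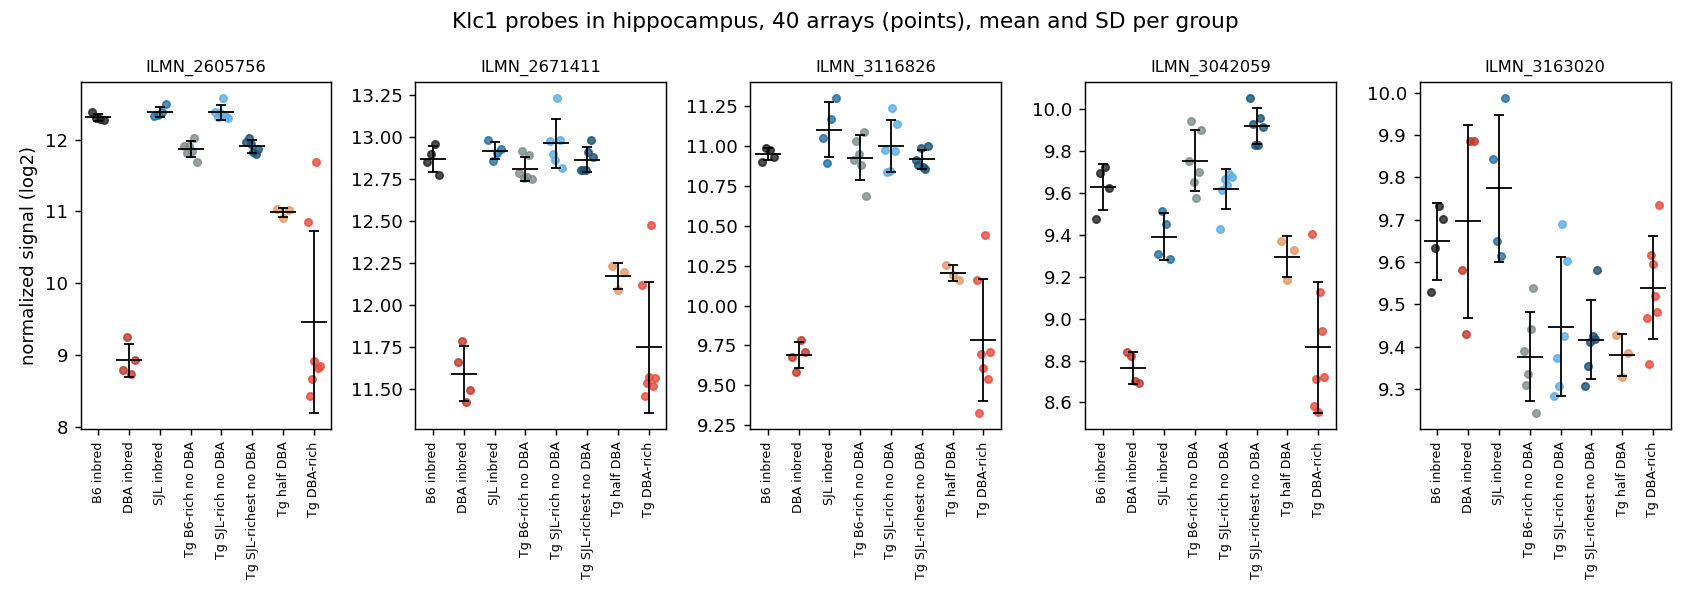
Normalized log2 signal of the 5 Klc1 probes (1 panel each) on 40 arrays, by group; points are arrays, and the bar and whiskers are the group's mean and SD. For ILMN_2605756 the DBA inbred mean is 8.93 against 12.31 in B6, and the DBA-rich Tg mean is 9.46; ILMN_3163020 reads 9.65 in B6 and 9.70 in DBA.

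Oligodendrocyte and myelin genes were lower in DBA than in B6. Of 13 measured members, 9 passed, all lower, and 12 did when adjusted over the list alone, among them Mal (log2 change -1.10 ± 0.12, SE) and Mobp (-1.02 ± 0.15), both encoding myelin-associated proteins. The list as a whole was lower (adjusted p = 8.23e-07, camera), with adjusted p = 0.815 with an estimated correlation. Plaque-associated microglial genes were lower too (adjusted p = 0.0302, with adjusted p = 0.815 with an estimated correlation), with 6 of 24 members lower and 2 higher; Fcer1g, encoding an Fc receptor chain, was undetected in DBA and at least 13.3-fold lower, and the lipoprotein lipase gene Lpl had a log2 change of 1.39. Those counts were again 6 and 2 when adjusted over the list alone. Against SJL, no list was called in DBA mice by camera, and the smallest adjusted p was 0.191.

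No other list was called between DBA and B6. Homeostatic microglial genes had 3 of 13 members lower in DBA and adjusted p = 0.194, excitatory neuron genes 4 of 13 lower and adjusted p = 0.0817, and interneuron genes 3 of 12 lower, 1 higher and adjusted p = 0.388. Amyloid precursor processing and clearance genes had 3 of 27 members lower, Ide (log2 change -0.72 ± 0.10, SE), Ece1 and Ncstn, and 1 higher, Sorl1. Kinesin and axonal transport genes had 4 of 26 lower, Klc1 with Kifap3 and Kif5a among them, and 1 higher, Klc3 at 0.86 ± 0.12. The adjusted p of both lists was 0.388. The astrocyte list had 1 of 10 members higher, the reactive astrocyte list 1 of 11 (Serpina3n), the thalamus list 1 of 9, the heat shock list 2 of 12 and the early gene list 1 of 12 (Fosb). Of the vessel and blood list 1 of 13 members was lower, and of the choroid plexus list 0 of 11 passed by limma. The interferon and antigen presentation list had 1 of 21 higher and 1 lower, mitochondrial respiration 1 of 17 higher and 2 lower, and genes known to vary between strains 2 of 5 higher (Alad and Glo1) and 3 lower. Adjusted over each list alone, the changed counts were 2 higher astrocyte genes, 3 higher and 1 lower thalamus genes, 1 higher excitatory gene and 4 lower interneuron genes.

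SJL and B6 mice differed at 1841 probes by limma, 952 of them lower in SJL, against 647 of 1385 on probes detected on all arrays. Spink8, Tmem68 and Cops8, a COP9 signalosome gene, were detected on no SJL array and stood at least 31.8-fold, 28.4-fold and 28.1-fold below B6. Zfp330 and Abhd16a were at least 22.7-fold and 24.7-fold lower and Zfp365 43.8-fold lower; of these, Zfp330 and Abhd16a were also undetected in DBA. Higher in SJL were 4930555G01Rik, H2-D1 and Trappc12, at least 14.8-fold, 7.18-fold and 4.72-fold, Ttl, at least 4.08-fold, Gm5797, detected on 1 of 4 B6 arrays, at least 9.05-fold, and Slc7a14, 7.55-fold. Oligodendrocyte genes were lower in SJL than in B6 (5 of 13 members, 9 adjusted over the list alone; adjusted p = 0.000879, with adjusted p = 0.728 with an estimated correlation). So were plaque-associated microglial genes (6 of 24 members lower and 2 higher, 8 and 2 adjusted over the list alone; adjusted p = 0.00735, with adjusted p = 0.728 with an estimated correlation); Trem2, a microglial receptor gene, had a log2 change of -0.92 ± 0.09 (SE). With runs as a block 1 oligodendrocyte member stayed lower in SJL, and 7 did adjusted over the list alone. That list's adjusted p was then 0.00573 (camera), with adjusted p = 0.928 with an estimated correlation. With the accession-named value table, limma called 0 probes between SJL and B6 (1026 at an unadjusted p under 0.05).

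Abeta40 was lower in Tg mice that carried DBA background. Its log10 level was 4.26 ± 0.30 in the 10 carriers and 4.79 ± 0.34 in the 18 DBA-free mice (SD), a difference of -0.536 and 3.44-fold on the linear scale (two-sided permutation p = 0.000390, 100000 resamples). By group, the level was 4.14 ± 0.27 in DBA-rich mice (n = 7), 4.53 ± 0.14 in 50% DBA mice (n = 3), 4.59 ± 0.37 in B6-rich, 4.80 ± 0.28 in SJL-richest and 4.99 ± 0.30 in SJL-rich mice (SD, n = 6 each). In the same order the SJL share was 9%, 42%, 37.5%, 84% and 69%. The comparison of carriers with DBA-free mice therefore does not tell more DBA from less SJL. On arrays 17 to 28 the difference was -0.822 (6 against 6 mice, exact permutation p = 0.00216). On arrays 1 to 16 it was -0.301 (4 against 12 mice, exact permutation p = 0.136), which did not pass the test.

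The inbred DBA differences were next sought in independent Tg mice with DBA background. By 1 probe each, DBA-rich mice had 42.1-fold less Enpp5 signal and 13.4-fold more Saraf signal than DBA-free mice. Another Saraf probe was lower in inbred DBA mice than in B6, so the Saraf value is one of that probe. Recurrence in Tg mice does not tell transcript levels from strain variants under probes. The other 7 lower probes named by rule were not detected on every DBA-rich array and have bounds: Abhd16a, detected on none, was at least 11.8-fold lower, Tesk1, detected on 1 of 7, at least 6.69-fold, and Psmb6, Rpl29, Serpini1, Casp9 and Il17d at least 6.76-fold, 5.96-fold, 5.81-fold, 5.14-fold and 4.11-fold. The other 7 higher ones were not detected on every DBA-free array: Lrrc57 was at least 7.01-fold higher, Noct 4.90-fold, H2-K1 4.68-fold, H2-Ab1 4.40-fold, Pdrg1 4.37-fold, H2-Ea 3.51-fold and Bfar 2.87-fold. With runs as a block, Enpp5 (log2 change -5.92), Saraf (3.60), Tesk1, Abhd16a, Psmb6, Serpini1, H2-K1 and H2-Ea still passed by limma, and Lrrc57, Pdrg1, Noct, H2-Ab1, Bfar, Casp9, Rpl29 and Il17d did not. Of the 606 probes distinct in inbred DBA mice, 93.7% had the same sign in DBA-rich Tg mice and 97.7% within arrays 17 to 28; 477 and 362 of them also passed the test there. Random probe sets matched on signal reached at most 66.7% and 70.6%. In 50% DBA mice 91.4% had the same sign and 252 probes passed, at a slope of 0.37 across probes against 0.58 in DBA-rich mice, a description across probes, which are not independent replicates.

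**Figure D3:**
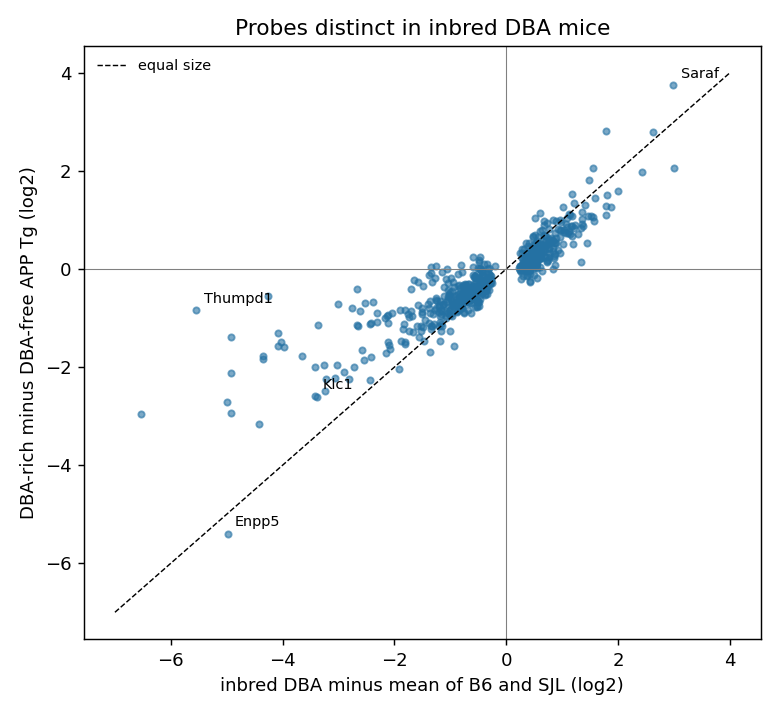
Log2 change of the 606 DBA-distinct probes in DBA-rich against DBA-free Tg mice (vertical) and in inbred DBA mice against the mean of B6 and SJL (horizontal), 1 point per probe; the dashed line marks equal size. Of the probes, 93.7% lie on the same side of 0 in both.

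In the DBA-rich contrast limma called 5025 probes, 2605 of them lower, but 475 (315 lower) with runs as a block and 982 (548 lower) against SJL-rich mice on arrays 17 to 28. The contrast on arrays 17 to 28 also set 9% SJL against 69% SJL. In the 50% DBA contrast limma called 1220 probes, 537 lower, against 162 (89 lower) with the block and 499 (319 lower) on arrays 1 to 16. With the value table, which agrees on all Tg arrays, the directions turned: 1915 of 4782 probes were lower in DBA-rich mice and 469 of 865 in 50% DBA mice. Without 50% DBA mouse 1 the 1220 probes became 525, without 50% DBA mouse 2 they became 147, and without DBA-rich mouse 1 they became 2639. Klc1 probe ILMN_2605756 was 6.01-fold lower in DBA-rich mice (log2 change -2.59 ± 0.27, SE, adjusted p = 1.26e-07, limma; -1.89 with the block, adjusted p = 0.00806). Its level was 9.46 ± 1.27 in DBA-rich mice (n = 7), 10.99 ± 0.07 in 50% DBA mice (n = 3) and 11.87 ± 0.12 in B6-rich mice (SD, n = 6). In 50% DBA mice its log2 change was -1.06 (adjusted p = 0.0755, and 0.0342 with the block), while ILMN_3116826 passed at -0.74 (adjusted p = 0.00170; -0.91 with the block, adjusted p = 0.00210).

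Oligodendrocyte genes were lower in both kinds of DBA-carrying mice. In DBA-rich mice 11 of 13 members passed, over all genes and adjusted over the list alone, with Mal at -0.58 ± 0.08 and Mbp, myelin basic protein, at -0.36 ± 0.06 (log2, SE). The list's adjusted p was 0.000255, with adjusted p = 0.886 with an estimated correlation, and with runs as a block 1 member passed (list adjusted p = 0.000155, with adjusted p = 0.598 with an estimated correlation). On arrays 17 to 28 the list's adjusted p was 0.000178, with adjusted p = 0.899 with an estimated correlation. In 50% DBA mice 5 members passed, 11 adjusted over the list alone (adjusted p = 1.12e-06, with adjusted p = 0.615 with an estimated correlation); with the block 1 passed and 12 did over the list alone (list adjusted p = 8.25e-09, with adjusted p = 0.412 with an estimated correlation). On arrays 1 to 16 its adjusted p was 3.91e-09, with adjusted p = 0.409 with an estimated correlation. Choroid plexus genes moved the other way without being called: their median log2 change was 0.79 in DBA-rich mice (adjusted p = 0.161, camera) and 0.43 in 50% DBA mice (adjusted p = 0.640), with 0.38 on arrays 17 to 28 and 0.59 on arrays 1 to 16 (the smaller adjusted p was 0.0800). One of them, Ttr, ranged from 9.91 to 15.45 over the Tg arrays. No other list was called in these contrasts over all Tg arrays. On arrays 1 to 16 excitatory neuron genes also shifted down in 50% DBA mice (adjusted p = 0.0172, with adjusted p = 0.870 with an estimated correlation).

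The last step of the series' design related expression to Abeta40 over the 28 Tg mice. Signals rose with Abeta40 for Hdc, the histidine decarboxylase gene (slope 1.10 ± 0.18 log2 per log10 unit of Abeta40, SE), Klc1 (ILMN_2671411, 0.95 ± 0.17), Slc17a7, a vesicular glutamate transporter gene (1.14 ± 0.23), Rtel1 (1.17), Zfp94 (1.04), Tnfrsf4 (0.86), Nvl (0.69), Rccd1 (0.64), Eef1aknmt (0.48) and Uap1l1 (0.47). Signals fell for Fam20b (-1.28), Arhgef15 (-1.16), Lst1 (-1.13), Lypd1 (-0.84), Slc27a2 (-0.82), Lbh (-0.75), Glo1, the glyoxalase 1 gene (-0.63), Mgst3 (-0.56), E2f1 (-0.51) and Dhdh (-0.42). By limma 205 probes passed, 130 of them positive, with adjusted p = 0.0116 for Klc1 ILMN_2671411 and ILMN_2605756 (slope 2.24 ± 0.40). Among the 227 strain-distinct probes 50 passed at an adjusted p of 0.001 over that list alone, 32 positive; the list was chosen on the inbred arrays. With runs as a block 2 probes passed, Hdc and Eef1aknmt, and 0 of the list; on arrays 17 to 28 157 passed, and on arrays 1 to 16 limma called 0 (770 at an unadjusted p under 0.05).

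Within backgrounds the association was not called. With the 5 backgrounds as a factor limma called 0 probes (541 at an unadjusted p under 0.05), and the slope of Klc1 ILMN_2671411 was 0.22 (unadjusted p = 0.139, limma). In the 18 DBA-free mice alone limma called 0 (1328 at an unadjusted p under 0.05) and in the 10 carriers 0 (626). By Klc1 ILMN_2605756 the 10 carriers lay in 2 separate sets of 5 mice. DBA-rich mice 2, 3, 4, 6 and 7 read 8.44 to 8.91, and DBA-rich mice 1 and 5 with the 50% DBA mice read 10.85 to 11.68. Each set has fewer than 6 mice, the least for which a correlation coefficient is given here, so none is given within them. Over all 10 carriers, which pools the 2 sets, the signal rose with Abeta40. It did not pass after adjustment (Pearson correlation, permutation, adjusted p = 0.0742). The DBA-free mice lay in 2 sets too, and correlations were computed within them after the values were seen, over a family of 7 probes of Klc1, App and Prnp. In the 12 B6-rich and SJL-richest mice (11.69 to 12.02) Pearson's r for ILMN_2605756 was 0.282 (permutation p = 0.376, adjusted 0.438), Spearman's rho 0.322 (permutation p = 0.309, adjusted 0.433), and r was 0.362 without the 2 mice farthest from the median Abeta40. In the 6 SJL-rich mice (12.30 to 12.58) r was -0.115 (exact permutation p = 0.764, adjusted 0.993), rho -0.0857 (exact permutation p = 0.919, adjusted 1) and r -0.164 without 2 mice. None of the 7 probes passed after adjustment. The 2 DBA-free sets also differ in background and array set. All B6-rich and SJL-richest arrays were in the earlier array set, and all SJL-rich arrays in the later one. The gap in Klc1 signal between them is therefore not told apart from the step between array sets. Within each of them the range of the signal is narrow. The correlations within sets therefore do not show whether signal and Abeta40 are related between the sets.

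**Figure D4:**
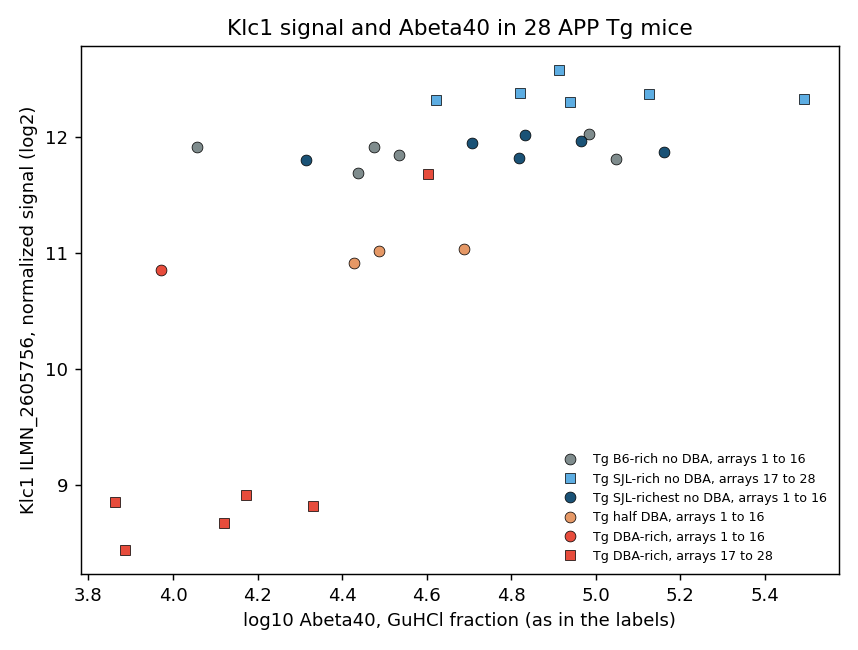
Normalized log2 signal of Klc1 probe ILMN_2605756 (vertical) against log10 Abeta40 (horizontal) in 28 Tg mice, 1 point each, coloured by background, with circles for arrays 1 to 16 and squares for arrays 17 to 28. Within the 12 B6-rich and SJL-richest mice r is 0.282 and within the 6 SJL-rich mice -0.115; neither passes after adjustment.

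Oligodendrocyte genes as a list rose with Abeta40. No member passed over all genes by limma, while 9 of 13 were positive adjusted over the list alone (adjusted p = 1.26e-08, with adjusted p = 0.296 with an estimated correlation). On arrays 1 to 16 its adjusted p was 0.000830, with adjusted p = 0.531 with an estimated correlation, and on arrays 17 to 28 it was 8.80e-09, with adjusted p = 0.238 with an estimated correlation. Other lists were called on arrays 1 to 16 alone: homeostatic microglial genes shifted up (adjusted p = 0.00580, with adjusted p = 0.528 with an estimated correlation), reactive astrocyte genes up (adjusted p = 0.0102, with adjusted p = 0.147 with an estimated correlation) and early genes down (adjusted p = 0.00580, with adjusted p = 0.528 with an estimated correlation). Within backgrounds the oligodendrocyte list again shifted up (adjusted p = 6.83e-11, camera, with adjusted p = 0.0929 with an estimated correlation). Of its 13 members, 5 were positive adjusted over the list alone. Also within backgrounds, and with no member passing over all genes, plaque-associated microglial genes shifted up (adjusted p = 0.0431, with adjusted p = 0.479 with an estimated correlation) and reactive astrocyte genes shifted up (adjusted p = 0.0431, with adjusted p = 0.423 with an estimated correlation). Activity-dependent early genes shifted down (adjusted p = 0.000143, with adjusted p = 0.312 with an estimated correlation), 4 of 12 adjusted over the list alone. With runs as a block the reactive astrocyte list had adjusted p = 0.129 within backgrounds. That block added calls for choroid plexus genes, up (adjusted p = 0.0284, with adjusted p = 0.657 with an estimated correlation), and interferon and antigen presentation genes, down (adjusted p = 0.0198, with adjusted p = 0.629 with an estimated correlation). Without backgrounds as a term it added reactive astrocyte genes, up (adjusted p = 0.0358, with adjusted p = 0.231 with an estimated correlation), and early genes, down (adjusted p = 0.0358, with adjusted p = 0.613 with an estimated correlation).

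Tg and inbred mice were compared with the SJL and DBA shares as terms. Of the genes with the most negative term for Tg mice, Hadhb, a mitochondrial fatty acid oxidation gene, was lower (log2 change -1.17 ± 0.23, SE), also with runs as a block (-0.54, adjusted p = 0.0338, limma). S100a8 (-1.33), Epha7 (-1.22), Zbtb18 (-1.19), Skp1 (-1.19), Dynlt3 (-1.18), Aldh6a1 (-1.17) and Tmem106b (-1.16) did not pass with the block; in each of these genes and Hadhb all 5 Tg group means lay below the 3 inbred means. Among the most positive terms, only Syne4 (0.92) had every Tg mean above the inbred means, and it did not pass with the block. The terms of the other genes rest on strain shares entered as straight lines on the log2 scale and are not read as higher levels in Tg mice. The Tg means of Zfp330 (1.65), Tmem68 (1.42) and Cops8 (1.22) lay within the inbred range, and those of Chchd4 (1.27), Thumpd1 (1.26), Erdr1 (1.02) and Btrc (0.93) overlapped it. Thumpd1, which passed with the block (2.98, adjusted p = 0.00336), had Tg means of 9.03 to 10.04 against 9.98 in B6, 9.99 in SJL and 4.44 in DBA. The App probe changed by -0.11 ± 0.03 (adjusted p = 0.00153) and by -0.02 with the block (adjusted p = 0.920). Limma called 7351 probes, 2958 lower, but 80 with the block (21 lower) and 2891 on arrays 17 to 40. Of the 4393 higher probes 2004 had every Tg mean above the inbred means, and of the 2958 lower ones 1501 had every Tg mean below; with the block these were 37 of 59 and 10 of 21. No gene list was called, with the smallest adjusted p at 0.249. No inbred mouse carried the transgene and no mixed mouse lacked it, so transgene and mixed breeding cannot be told apart.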

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

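Tests chosen only after the results were seen are those of the table columns, of array sets, of sister probes, of B6-distinct and SJL-distinct probes and of regrouped samples; those of shared DBA background, of SJL skew and of recurrence were written beforehand. The outcome that would count against the sister-probe explanation was also reworded after its value was known.

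Single arrays stood apart from their group in 4 of 74 groups of values tested, where 3.70 are expected by chance. Klc1 probe ILMN_2605756 read 12.58 in SJL-rich mouse 4, against 12.38 in the next, and probe ILMN_3042059 read 9.43 in SJL-rich mouse 1, against 9.62. The choroid plexus gene Ttr read 12.14 in B6 inbred mouse 3, where the other B6 mice read 14.83 to 15.31, and 11.57 in DBA-rich mouse 7, where the others read 14.51 to 15.45. For 1 probe, Atxn1 ILMN_1254409, the Abeta40 slope differed between carriers and DBA-free mice (difference 1.34 ± 0.23, SE, adjusted p = 0.0469, limma; 1930 probes at an unadjusted p under 0.05). With runs as a block that difference was 1.20 ± 0.25 and did not pass (adjusted p = 0.505).

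The inbred arrays differ in strain between the 2 deposited tables. The 982 probes that part DBA-rich from SJL-rich Tg arrays, on which both tables agree, were used to score the inbred arrays. Assigned by number, 4 of 4 DBA arrays scored above all SJL arrays (0.42 to 0.46 against -0.34 to -0.31, exact permutation p = 0.0286), which argues against misplaced numbered columns. Assigned by accession, 0 did (exact permutation p = 0.657), so misplaced accession-named columns are a candidate explanation. By accession the scores of each strain also ran wide, from -0.11 to 0.44 in DBA, -0.33 to 0.46 in SJL and -0.34 to -0.11 in B6. By number those of B6 ran from -0.13 to -0.09. These values argue against the accession order of the inbred arrays. This test came after both sets of results, and the tables do not say where an order was changed.

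Abeta40-associated probes may reflect DBA background, because Abeta40 and expression both follow it. The SJL share differs between the same groups, so the values below do not tell more DBA from less SJL. Over the 205 probes the median slope within backgrounds was 0.282 of the pooled slope. Within backgrounds 184 kept their sign, 27 of them at an unadjusted p under 0.05 by limma. Of the 205 probes, 132 were strain-distinct in inbred mice without the transgene. The 205 probes were chosen by their pooled slope on these same arrays, which favours kept signs and can lower the ratios. On arrays 1 to 16 alone 107 of them kept their sign at an unadjusted p under 0.05 by limma. With runs as a block the median slope was 0.842 of the pooled one and all 205 kept their sign. Within that limit this argues against array sets as the whole cause. That block left 2 calls: the slope of Klc1 ILMN_2605756 went from 2.24 ± 0.40 to 1.89 ± 0.40 (SE), a smaller slope with an error of like size. An effect of Klc1 or any other gene on Abeta40 stays open, as no test here separates it from linked DBA variants.

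Among strain-distinct probes, those lower in DBA outnumber those higher, which strain variants under probes designed on B6 sequence could produce. At the series' thresholds 69.3% of probes distinct in B6 were higher in B6 and 71.4% of those distinct in SJL were lower in SJL, which makes it a candidate; at 0.05 alone the shares were 53.3% and 62.4%, so it stays open. Among all calls between SJL and B6 the share lower in SJL was 0.517, between the bounds set beforehand of 0.5 and 0.55, and decides nothing. Of probes lower in DBA whose gene has another tested probe, a share of 0.381 had it called lower as well, against 37.1% for probes higher in DBA (two-sided Fisher's exact p = 0.894), which decides nothing either. Lower transcript levels in DBA stay open, since no probe was matched to strain sequences.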

How the results depend on the processing

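Runs of 8 arrays, array sets and the normexp version of the value table were chosen after seeing the data; all other alternatives were planned. The cause of a change was not tested unless stated. Named-gene values kept direction and call in 139 of 139 cases with trend and robust variances, without a probe filter, and with quantile normalization and no background correction.

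With the value table in log2, the counts were 78, 85 and 0 for DBA against B6, DBA against SJL and SJL against B6 (limma, 1026 of the last at an unadjusted p under 0.05), 45 strain-distinct probes and 0 at the series' thresholds; with normexp they were 15, 54, 0 (1082 at an unadjusted p under 0.05), 13 and 0. By construction that table assigns 6 of the 12 inbred arrays to another strain than the non-normalized one. Of 139 named-gene values, 50 weakened and 22 reversed under that table, in log2. For SJL against B6 these were H2-D1 -0.55, Ttl -0.0127 and Cops8 0.0758. For DBA against SJL they were Klc1 0.19 (ILMN_2671411), 0.10 (ILMN_2605756) and 0.22 (ILMN_3042059), Stab2 -0.20, H2-K1 -0.21, Ccr6 -0.0277, H2-Ea -0.23, Arhgef15 -0.16, Ap5b1 -0.0291, Fpr2 -0.11, Psmb6 0.32, Thumpd1 0.0579, Enpp5 0.34, Fgfr1op2 0.27, Atf4 0.39, Tesk1 0.44, Stard7 0.23, Rps3 0.26 and Mettl14 0.0804.

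With probes detected on all 40 arrays, 119 passed the series' thresholds and 127 were associated with Abeta40, from fewer probes tested; without a filter 108 were. The methods' t-test gave 111 probes at the series' thresholds; at an unadjusted p under 0.05 it called 3154, 2746 and 3404 probes for the 3 strain pairs, and 1376, 1104 and 1565 after Benjamini-Hochberg. The DBA-rich count was 1017 with continuous percentages and the 50% DBA count 215 against SJL-richest mice alone. Abeta40 counts were 0 over all probes (limma) and 0 among strain-distinct ones in DBA-free mice (1328 at an unadjusted p under 0.05), in carriers (626) and with percent DBA as a term (653); they were 98 and 30 without the 2 mice farthest from the median, and Pearson correlation gave 14 among strain-distinct probes.

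With runs as a block, Abeta40 counts were 2 and 0, the DBA-rich count 475, the 50% DBA count 162 and the Tg against inbred count 80; 42 of 139 named values weakened and Tmem68 reversed to -0.41 for Tg against inbred. Of the DBA-rich calls 419 were shared by both fits. Strain counts stayed within 1.5 times. Within sets, DBA-rich calls were 982, 50% DBA calls 499, Tg against inbred calls 2891, Abeta40 calls 0 on arrays 1 to 16 (limma, 770 at an unadjusted p under 0.05) and 25 among strain-distinct probes on arrays 17 to 28, with 0 of them on arrays 1 to 16. The Abeta40 difference was -0.301 on arrays 1 to 16. Gene list calls went from 11 to 0 with an estimated correlation (camera, 5 at an unadjusted p under 0.05).

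Leaving out single arrays gave 1331 to 1739 probes for DBA against B6, 1249 to 1502 for DBA against SJL, 1453 to 1852 for SJL against B6, 504 to 587 strain-distinct probes, 207 to 221 at the series' thresholds, 4226 to 6400 for DBA-rich mice, 147 (without 50% DBA mouse 2; 525 without mouse 1) to 2639 (without DBA-rich mouse 1) for 50% DBA mice, and 6768 to 7373 for Tg against inbred. Only the 12 inbred arrays were left out in turn for the strain counts and for Tg against inbred. For the DBA-rich and 50% DBA counts only the 10 carriers were. The slide block was not run, as no column names a slide. No paired analysis was possible because replicate numbers follow accession order. Signals near background limit folds to bounds.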

Other observations

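Tests of regrouped arrays, within array sets and with runs as a block were chosen after the results were seen, and the bound on the recurrence share was written beforehand.

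Leading members of the gene lists also set SJL or B6 mice apart. The microglial gene Ly86 was higher in DBA than in SJL (log2 change 1.04 ± 0.08, SE, adjusted p = 1.79e-06, limma) and lower in SJL than in B6 (-0.94, adjusted p = 4.66e-06), while DBA and B6 differed by 0.10 (adjusted p = 0.542). In DBA-rich Tg mice it was higher by 1.05 ± 0.14, and by 0.86 with runs as a block (adjusted p = 0.0474). The immunoproteasome gene Psmb9 was detected in B6 alone, at least 1.46-fold above DBA (adjusted p = 3.14e-05) and 1.36-fold above SJL (adjusted p = 7.67e-05). Aph1b, a gamma-secretase subunit gene, was undetected in SJL and at least 5.26-fold lower than in B6 (adjusted p = 2.74e-10, limma). Among neuronal genes, Dlg4, the postsynaptic density scaffold gene, was lower in DBA than in both strains (-1.73 in each) and in DBA-rich Tg mice (-1.27 ± 0.27; -2.63 with the block, adjusted p = 2.26e-06). Rgs5, a pericyte gene, was higher in SJL than in B6 (1.36 ± 0.10, adjusted p = 6.53e-07).

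Of the strain-distinct probes a share of 0.937 had the same sign in DBA-rich Tg mice, where 477 of 606 passed the test, above the highest of 1000 matched random sets, so unrelated lists are excluded as the cause of that share.

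Regrouping the arrays without regard to array set never gave as many calls as the real groups. For DBA against B6, DBA against SJL and SJL against B6 this was 1 of 35 splits (the real one), with 1672, 1523 and 1841 probes against 53, 1 and 4 in the highest other split. In 1 of 100 splits each, the real one, the same held for strain-distinct probes (606 against 0), those at the series' thresholds (227 against 0), DBA-rich mice (5025 against 29), 50% DBA mice (1220 against 6) and Tg against inbred mice (7351 against 1768). For the inbred counts the other splits mix the strains, which raises the spread within groups and lowers their counts. They show that the real split stands out, for an array order kept after its counts were seen. Tg groups largely follow the array sets, which those splits mix, so for the Tg counts the splits do not tell groups from sets. Arrays 17 to 40 against 1 to 16 gave 9251 calls by limma, more than the 7351 of Tg against inbred mice. Later against earlier DBA-free Tg arrays gave 6424, more than the 5025 of DBA-rich mice. All inbred arrays are in the later set, and with runs as a block the strain pairs gave 1819, 1324 and 1579 probes, so array sets can be excluded as the whole cause of the inbred counts. All 4 SJL arrays lay in the last run, while B6 and DBA each had 2 arrays there and 2 in the run before. Without the block, the 2 contrasts with SJL are therefore partly contrasts of runs. Within 1 set limma still called 982 probes for DBA-rich mice, 499 for 50% DBA mice and 2891 for Tg against inbred mice. The step between the 2 sets is therefore not the whole cause there. Runs within a set are not excluded as a cause. All 6 SJL-rich arrays lay in 1 run with 2 of the 6 later DBA-rich arrays, and the other 4 lay in the next run. On arrays 17 to 40 every Tg array came before every inbred array. With runs as a block the full counts of 5025, 1220 and 7351 became 475, 162 and 80. Of the DBA-rich, 50% DBA and Tg against inbred calls, 82.5%, 99.6% and 78.7% then kept their direction. How much of the full counts comes from the arrays stays open.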
